A study of Danio rerio with 4 samples.

How the data were processed

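RNA of rods, cones and pineal photoreceptors of adult zebrafish was compared on 4 Agilent zebrafish expression arrays with 2 colours. Per the labels' protocols, fluorescent cells of each transgenic line were purified, RNA was extracted with RNeasy columns and labelled with Cy3 or Cy5 by the Quick-Amp method. Cone extract 1 and rod extract 1 shared an array, as did cone extract 2 and rod extract 2, pineal extract 2 and rod extract 1, and pineal extract 1 and rod extract 2. Rod extract 1 always carried Cy3 and rod extract 2 always Cy5. Cell types were assigned from the labels of each channel, and the direction of each ratio from the labels of the dyes. Samples are biological replicates per the series' design text, 2 per cell type.

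The intensity values, mean spot signals and median local backgrounds of both channels, were made by the authors with Agilent Feature Extraction 10.5.1.1, per the submitters' processing notes, and carry no normalization. The processed intensities in the same tables were background-subtracted, spatially detrended and dye-normalized by that program, per the file headers. The log10 values of the deposited series table were derived by the authors from the program's log ratios, which are log10 of Cy5 over Cy3 per the file headers. Set against each array's log ratios, the columns correlated with r = -0.994 and 0.999 for cone replicates 1 and 2 and 0.998 and -0.999 for pineal replicates 1 and 2, below 0 where rod RNA carried Cy3, so the table gives rod over cone or rod over pineal photoreceptor on every array. The column medians were 0.0519 and 0.0115 for cone replicates 1 and 2 and 0.0227 and 0.0143 for pineal replicates 1 and 2. The series table and the processed intensities gave the same medians of log2 differences over the genes tested below. These were -0.0569 in cones against rods, -0.00977 in pineal photoreceptors against rods and 0.0447 in pineal photoreceptors against cones. Both also called 3999, 4797 and 2934 genes different, so for the tested genes the table shows no centring beyond the processed intensities. Per channel, 28.7% to 43.8% of features were well above background, more in Cy5 than in Cy3, which together with the number of arrays limits what dim genes can show.

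From the unprocessed intensities, background was corrected with normexp and an offset of 50, log ratios were normalized by loess within each array with control spots at weight 0, spots marked as outliers were dropped and spots of 1 probe were averaged. All ratios were turned to cone or pineal photoreceptor minus rod. Names came from the accessions and symbols on the array through a RefSeq table of assembly GRCz12tu, used for names only. Of 43603 probes, 16072 matched a reference symbol by accession and 19674 had a gene symbol in all, covering 13267 symbols. Where no match was found, for 22499 probes, the name was kept as the file gave it. A gene was represented by its probe with the highest mean brightness. A probe was kept if well above background in every channel of at least 1 cell type, which left 13184 of 35969 names, and 40 probes lacked a value on some array.

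Tests were run with limma 3.58.1 in R 4.3.3, with lmFit and eBayes on all 4 arrays, 1 coefficient each for cone minus rod and pineal photoreceptor minus rod, and pineal photoreceptor minus cone as their contrast. Benjamini-Hochberg adjustment was over the genes tested and the threshold 0.05. The fit had 2 residual degrees of freedom and a prior of 4.73. Arrays sharing a rod extract share RNA, and their deviations from the cell type means correlated across genes with r = 0.508 and Spearman's rho = 0.444. The rod extract number, which is also the dye orientation, was therefore run as a replicate block beside the fit without it. With the block, p-values of the comparisons with rods leave out the spread between rod extracts. Where a probe was not well above background in any channel of a cell type, the difference is also given as at least N-fold. That is the mean level of the brighter cell type over all its channels, divided by the mean, per array, of the dimmer probe's own level or the lowest signal well above background, whichever was higher. Levels and differences draw partly on different arrays, so a bound can exceed the fold of its log2 difference and is then no floor for it. Levels per channel were taken after loess and Aquantile. Simulated data for the comparison of cones and rods, with 13184 genes, 200 of them changed and 20 runs, gave back 90.6% of 2-fold and 99.95% of 4-fold changes, with 6.09% false among those called.

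Before the data were examined, 21 gene lists, the rule for named genes, the tests and their alternatives were fixed. The lists cover rod and cone phototransduction, non-visual opsins, serotonin and melatonin synthesis, transcription factors, the circadian clock, retinoid metabolism, outer segment and cilium, the synapse, glycolysis and creatine kinase, oxidative phosphorylation, cytoplasmic ribosomal proteins, and stress and immediate early genes. Others hold markers of Mueller glia, pigment epithelium and melanophores, bipolar cells, amacrine, horizontal and ganglion cells and other neurons, blood and immune cells, vessels, connective tissue and epithelium, oligodendrocytes and brain glia, and cell cycle and progenitors. Some genes are in more than 1 list, and many markers of other cells are also expressed in photoreceptors. The array held a probe for most members, from 17 of 33 non-visual opsins to 82 of 82 oxidative phosphorylation genes. Lists were tested with camera at its preset correlation, adjusted over the 21 lists, with the correlation estimated as an alternative. The alternative rests on the 2 residual degrees of freedom of the fit, which leaves it little power. For outer segment and cilium in pineal photoreceptors against rods, the estimate was only 0.000172, yet the unadjusted camera p rose from 0.00113 to 0.0594. A call lost there does not show that correlation between genes made it. None of the 7, 4 and 7 calls in cones against rods, pineal photoreceptors against rods and pineal photoreceptors against cones held with an estimated correlation, where the lowest adjusted p were 0.483, 0.612 and 0.534, and 1, 0 and 1 lists had an unadjusted p under 0.05. The rotation test fry, which asks whether a list's genes move 1 way on balance, passed 9, 11 and 11 lists, and its mixed form, for changes in either direction, 19, 21 and 20. A list of genes induced by interferon was written after the largest differences had been seen.

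Named genes were, per comparison, the 3 genes driving the fluorescent protein, the 8 largest rises and 8 largest falls among genes past the threshold with 1 direction on both arrays and a gene symbol, and up to 3 members of each list past the threshold with the largest change. For genes set apart in 1 cell type they were the 8 with the largest smaller difference. Members of lists were left out for length from the smallest change up, and genes named outside the rule are said to be chosen after their values were seen. Alternatives were the processed signals, the series table, an offset of 10, median centring, scaling between arrays, no filter, a filter in all 3 cell types, the mean of a gene's probes, the replicate block, each comparison on its own arrays, separate channels with an intraspot correlation of 0.329 (statmod 1.5.0), eBayes with trend and robust, stricter thresholds and leaving out each array. Median centring with the replicate block was added after seeing the data. Both comparisons with rods were related by correlation across genes, beside 100 simulations of unchanged cell types sharing the rod extracts. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.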

Results

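Gene expression was measured in 3 kinds of photoreceptors of adult zebrafish of the Ekkwill strain. Rods came from Tg(rho:egfp) fish, cones from Tg(gnat2:egfp) fish and pineal photoreceptors, the light-sensing cells of the pineal organ, from Tg(exorh:EGFP) fish. In each line the promoter of the named gene drives green fluorescent protein, and the fluorescent cells were purified before RNA was extracted. Each cell type therefore came from 1 line, and cell type and line cannot be told apart. The design text gives 2 biological replicates per cell type. RNA of cones or pineal photoreceptors was hybridised against RNA of rods on 4 Agilent arrays with 2 colours, 2 arrays per comparison with rods, and the dyes were swapped between them. All 4 arrays were on 1 slide and in 1 scan, so slide and scan could not be tested as batches. Between 28.7% and 43.8% of 43803 features were well above background per channel and 0 were saturated. Of 35969 names with a probe, 13184 were tested, 7465 of them under a gene symbol. Values are mean log2 differences ± SD over n = 2 arrays, and adjusted p-values are from limma. The number of arrays limits the precision.

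The genes whose promoters marked the cells were read first. Transducin alpha gnat2, the cone transducin, was higher in cones than in rods by 6.95 ± 0.31 (adjusted p = 1.19e-06). It was also higher in pineal photoreceptors than in rods, by 2.55 ± 0.16, and stood at -4.40 ± 0.15 in pineal photoreceptors against cones. The pineal opsin exorh differed by -0.25 ± 0.17 between cones and rods (adjusted p = 0.205, and -1.79 with adjusted p = 0.0381 with the processed signals), with cones below background, and by 4.38 ± 0.27 between pineal photoreceptors and rods (adjusted p = 2.87e-06). Rod RNA itself gave a clear exorh signal on the pineal arrays. Before dye normalization its exorh signal was 63.9 and 55.3 on the cone arrays and 1854 and 12558 on the pineal arrays, for rod extracts 1 and 2. The exorh differences of pineal photoreceptors are low estimates for that reason, and a bound of at least 8.2-fold between rods and cones draws on the rod signal of the pineal arrays. Against cones, the contrast through rods was 4.63 ± 0.10, and the channel levels put exorh at least 1175-fold higher in pineal photoreceptors. The probe of rhodopsin, rho, was not well above background in any of the 8 channels and so checks nothing. The probes of the ultraviolet opsin opn1sw1 and of the pineal enzyme aanat2 were likewise not tested.

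The first comparison asked which transcripts differ between cones and rods. Apart from gatd3l, which is in no list, the largest rises in cones were of cone phototransduction and outer segment genes. They were the cone arrestin arr3a (7.47 ± 0.26), the red opsin opn1lw1 (7.42 ± 0.68), gatd3l (7.38 ± 0.28) and the transducin gamma subunit gngt2a (7.21 ± 0.17). The blue opsin opn1sw2 (7.21 ± 0.066), gnat2 itself, the green opsin opn1mw2 (6.91 ± 0.036) and the disc-rim tetraspanin prph2a (6.76 ± 0.38) followed. The largest falls in cones were of the rod phosphodiesterase gamma subunits pde6ga (-5.19 ± 0.55) and pde6gb (-4.44 ± 0.034), the transcription factor mafba (-4.62 ± 0.40) and the elongation factor eef1a1b (-4.38 ± 0.13). The rod arrestin saga (-4.25 ± 0.46), the disc-rim tetraspanin rom1b (-4.24 ± 0.25), the rod nuclear receptor nr2e3 (-4.16 ± 0.035) and the cyclooxygenase ptgs2a (-4.13 ± 0.44) completed these. Adjusted p of these 16 genes lay between 8.22e-07 and 4.02e-05, and each had the same direction on both arrays.

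Across all genes, 4966 of 13184 differed at adjusted p 0.05, 2623 higher and 2343 lower in cones, which put 52.8% of them higher. At 2-fold or more, 996 were higher and 644 lower. The log2 ratios of both arrays correlated across genes with r = 0.914, genes not being independent replicates. The split into higher and lower depended on the dye normalization, since median centring with the replicate block, chosen after seeing the data, put 29.0% of 5698 genes higher and the block alone 50.9% of 7101. Median centring without the block left 0 genes in limma in each of the 3 comparisons, with 478, 648 and 326 genes at an unadjusted p of 0.05.

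Of 26 cone phototransduction genes, 22 were higher in cones, 1 lower and 3 not passing (22 higher and 1 lower adjusted over the list alone), with camera adjusted p = 5.39e-16, adjusted p = 0.483 with an estimated correlation. The G protein signalling regulator rgs9b (-2.57 ± 0.31), chosen after its value was seen, was the member that fell. Of 18 rod phototransduction genes, 15 were lower, 2 higher and 1 not passing (2 higher and 15 lower adjusted over the list alone), with camera adjusted p = 2.78e-08, adjusted p = 0.483 with an estimated correlation. The higher members were the recoverin rcvrn2 (5.74 ± 0.17) and rgs9a (3.71 ± 0.096), the latter chosen after its value was seen. Among 40 transcription factors of photoreceptors and the pineal organ, 19 rose, 8 fell and 13 did not pass (19 higher and 8 lower adjusted over the list alone), with camera adjusted p = 0.0188, adjusted p = 0.62 with an estimated correlation. They included six7 (6.70 ± 0.44), a homeobox factor needed for green opsin expression, the nuclear receptor nr2f6b (5.87 ± 0.23) and the thyroid hormone receptor thrb (4.37 ± 0.30), needed for red opsin expression. Among 26 genes of the photoreceptor synapse, 10 rose, 1 fell and 15 did not pass (10 higher and 1 lower adjusted over the list alone), with camera adjusted p = 0.00849, adjusted p = 0.483 with an estimated correlation. The complexin cplx4a (4.01 ± 0.10), the calcium channel subunit cacna2d4a (2.1 ± 0.71, at least 4.14-fold) and the ribbon gene ctbp2a (2.01 ± 0.11) led them.

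Of 78 oxidative phosphorylation genes, 29 rose, 4 fell and 45 did not pass (32 higher and 6 lower adjusted over the list alone), with a median of 0.31 that median centring turned to -0.13. The list passed camera with camera adjusted p = 0.00849, adjusted p = 0.483 with an estimated correlation. That call was lost with the processed signals (adjusted p = 0.0727), with median centring (adjusted p = 0.809) and without cone replicate 2 (adjusted p = 0.0674). Its largest members were cox6b1 (-1.35 ± 0.32), cox7a1 (-1.22 ± 1.06), which did not pass with the processed signals (-1.57, adjusted p = 0.0536) or without cone replicate 2 (-0.47, adjusted p = 0.119), and uqcrq (1.1 ± 0.11). The lists that follow had no camera call, and counts are of members higher and lower. Counts adjusted over the list alone were the same except where given. Outer segment and cilium genes counted 9 and 17 of 47 (9 and 19 adjusted over the list alone), camera adjusted p = 0.14, with prph2a, rom1b and rom1a (-4.03 ± 0.13) foremost. Serotonin and melatonin synthesis counted 3 and 4 of 12 (3 and 5 adjusted over the list alone), camera adjusted p = 0.185, with the N-acetyltransferase aanat1 (-3.21 ± 0.30), the decarboxylase ddc (-2.46 ± 0.26) and the monoamine oxidase mao (-2.39 ± 0.31) lower. Non-visual opsins counted 3 and 0 of 8, camera adjusted p = 0.352, led by opn6a (3.01 ± 0.63), opn6b (2.65 ± 0.031) and the melanopsin opn4.1 (1.32 ± 0.49). Retinoid metabolism counted 4 and 6 of 22, camera adjusted p = 0.669, with dhrs3b (-2.75 ± 0.53) and the retinol dehydrogenase rdh10b (2.31 ± 0.40) foremost. Glycolysis and creatine kinase genes counted 12 and 7 of 32, camera adjusted p = 0.352, with the mitochondrial creatine kinase ckmt2a (2.59 ± 0.051) and the enolase eno2 (-2.41 ± 0.42) foremost. Clock genes counted 6 and 5 of 31 (6 and 4 adjusted over the list alone), camera adjusted p = 0.811. Cytoplasmic ribosomal proteins counted 3 and 4 of 78 (0 and 0 adjusted over the list alone), camera adjusted p = 0.651, and cell cycle and progenitor genes 3 and 3 of 16, camera adjusted p = 0.651.

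Genes that respond to tissue dissociation also differed. Of 32 stress and immediate early genes, 22 rose in cones, 1 fell and 9 did not pass (22 higher and 3 lower adjusted over the list alone), with camera adjusted p = 1.29e-06, adjusted p = 0.483 with an estimated correlation. The immediate early genes egr1 (4.45 ± 0.26), fosab (3.61 ± 0.27) and ier2b (3.27 ± 0.11) led them. Markers of other cell types moved as well. Of 9 markers of blood and immune cells, 5 were lower in cones than in rods and 4 did not pass, none being higher (6 lower adjusted over the list alone), with camera adjusted p = 0.0188, adjusted p = 0.592 with an estimated correlation. The chemokine ccl34b.1 (-2.12 ± 0.27), coro1a (-1.33 ± 0.14) and lcp1 (-1.01 ± 0.42) fell most, and the list missed the threshold without cone replicate 1 (adjusted p = 0.0577). Markers of bipolar cells counted 0 and 3 of 7 (0 and 4 adjusted over the list alone), camera adjusted p = 0.0516 (adjusted p = 0.0323 with the replicate block and 0.0171 without cone replicate 2), with trpm1b (-4.02 ± 0.45) and grm6b (-1.20 ± 0.36, at least 2.2-fold) lower. Markers of Mueller glia counted 3 and 5 of 15, camera adjusted p = 0.651, with glulb (1.92 ± 0.35) and glula (-1.58 ± 0.13) parting. Markers of amacrine, horizontal and ganglion cells and other neurons counted 3 and 4 of 19, camera adjusted p = 0.699, with kctd12.1 (4.85 ± 0.15) and rbfox1 (3.89 ± 0.48) higher. Markers of vessels, connective tissue and epithelium counted 2 and 1 of 10, camera adjusted p = 0.811, with pecam1a (-1.26 ± 0.17) lower. Pigment epithelium and melanophore markers counted 0 and 2 of 7, camera adjusted p = 0.333, and oligodendrocyte and brain glia markers 0 and 2 of 8 (0 and 1 adjusted over the list alone), camera adjusted p = 0.241. Other settings gave calls to some of these lists. Median centring did so for bipolar cells (adjusted p = 0.00766), non-visual opsins (0.033), serotonin and melatonin synthesis (0.0433) and ribosomal proteins (0.0433), and leaving out cone replicate 2 for the last pair (0.0375 and 0.0117). Testing without the filter on dim probes did so for outer segment and cilium (0.0219) and bipolar cells (0.0133), the mean of a gene's probes for bipolar cells (0.0487), and leaving out either pineal replicate for bipolar cells (0.0456). Median, mean and camera direction differed in sign for 3 lists without a call. They were non-visual opsins (median -0.0091, 0.28 with the processed signals and 0.017 with median centring, mean 0.80, camera up), clock genes (median -0.039, mean 0.13, camera up) and neuron markers (median -0.14, mean 0.31, camera down).

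A group outside the fixed lists stood out among the largest differences, the genes induced by interferon. A list of them was written after the largest differences had been seen, and 35 members were tested. In cones 30 were higher than in rods, 2 were lower and 3 did not pass (the same adjusted over the list alone), with a median of 2.03. The ubiquitin-like isg15 (6.13 ± 0.26), ifi27.1 (5.66 ± 0.37), ifi27.2 (5.11 ± 0.051), the signal transducer stat1b (4.0 ± 0.21), xaf1 (3.92 ± 0.034) and the interferon regulatory factor irf7 (3.33 ± 0.15) were among them, chosen after their values were seen. The antiviral gene mxa (3.17 ± 0.072, at least 9.29-fold) and ifit16 (3.56 ± 0.55, at least 10.8-fold) were not well above background in rods. The bound of mxa, from the levels of all rod channels, lies above the fold of its difference. The size depended on the processing, the median being 4.31 with the processed signals and 2.87 with an offset of 10. Without isg15, ifi27.1, ifi27.2 and ifi27.7, which had drawn attention to the group, 26 of 31 were higher and 2 lower, with a median of 1.87. In pineal photoreceptors 3 of the 35 were higher than in rods and 7 lower (3 and 3 adjusted over the list alone). Against cones 27 were lower in pineal photoreceptors and 8 did not pass, none being higher (the same adjusted over the list alone), with a median of -1.89. That median was -4.33 with the processed signals and -2.45 with an offset of 10. Some members lay below background in 1 cell type, and with these at their bound the medians were 2.03 for cones against rods and -1.95 for pineal photoreceptors against cones.

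**Figure D1:**
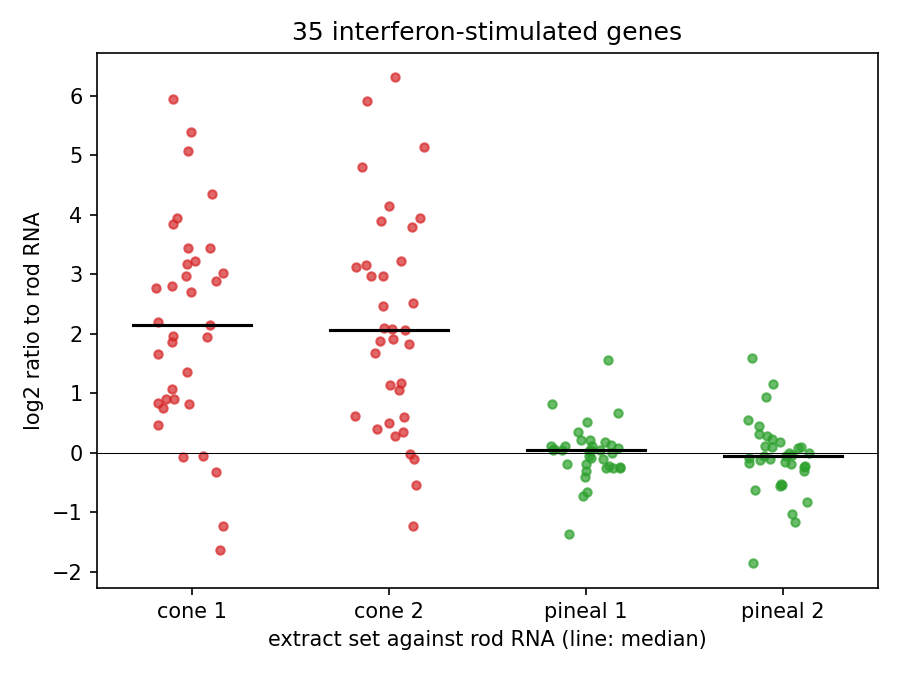
Log2 ratio to rod RNA (vertical axis) of 35 genes induced by interferon, 1 point per gene, for each cone array (red) and pineal photoreceptor array (green), with the median as a line. The medians are 2.14 and 2.06 on the cone arrays and 0.046 and -0.054 on the pineal arrays of pineal replicates 1 and 2.

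The second comparison set pineal photoreceptors against rods. Being a low estimate, the difference of exorh is ranked too low here and below. Among 16 other genes bright in pineal and dark in rod RNA, some also gained rod signal on the pineal arrays. The gain was largest for kcnd3, 2.25% and 19.1% of the pineal signal for rod extracts 1 and 2 before dye normalization. Other differences may therefore be low estimates too, and the order of the rises is uncertain. The largest rises in pineal photoreceptors were of tph2 (7.47 ± 0.056), a tryptophan hydroxylase of serotonin synthesis, ptprn2 (6.67 ± 0.78), the recoverin rcvrnb (6.64 ± 0.72) and pcp4l1 (6.4 ± 0.0099). The cone opsin kinase grk7a (6.10 ± 0.11), the sulfotransferase sult4a1 (6.02 ± 0.085), the S-adenosylhomocysteine hydrolase ahcy (5.89 ± 0.21) and the cone phosphodiesterase pde6c (5.71 ± 0.52) followed. The largest falls were of the disc-rim tetraspanins rom1b (-7.80 ± 0.093), rom1a (-7.07 ± 0.00050) and prph2b (-6.46 ± 0.83), and of the N-acetyltransferase aanat1 (-7.70 ± 0.57). Phosducin pdca (-6.99 ± 0.71), the guanylate cyclase activator guca1b (-6.74 ± 0.83), mafba (-5.71 ± 0.84) and skib (-4.74 ± 0.84, at least 24.6-fold) also fell. Adjusted p of these 16 genes lay between 9.41e-07 and 1.72e-05, each with 1 direction on both arrays.

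In all, 5884 genes differed, 3306 higher and 2578 lower in pineal photoreceptors, which put 56.2% of them higher. At 2-fold or more, 1292 were higher and 777 lower, and the log2 ratios of both arrays correlated across genes with r = 0.942. Without pineal replicate 2 the count was 3284.

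Of 18 rod phototransduction genes, 10 were lower in pineal photoreceptors, 3 higher and 5 not passing (3 higher and 10 lower adjusted over the list alone), with camera adjusted p = 0.0305, adjusted p = 0.645 with an estimated correlation. The call was lost with the processed signals (adjusted p = 0.0878) and with the mean of a gene's probes (adjusted p = 0.0646). The members with the largest changes were guca1b, rcvrnb and rcvrn2 (5.02 ± 0.031), both recoverins being higher. Of 47 outer segment and cilium genes, 20 fell, 10 rose and 17 did not pass (10 higher and 22 lower adjusted over the list alone), with camera adjusted p = 0.0139, adjusted p = 0.612 with an estimated correlation and adjusted p = 0.0547 with the processed signals. The stress and immediate early list had 20 of 32 higher, 6 lower and 6 not passing (20 higher and 6 lower adjusted over the list alone), with camera adjusted p = 0.0139, adjusted p = 0.612 with an estimated correlation. Its foremost members were egr1 (4.95 ± 0.28), socs3a (4.05 ± 0.61) and fosab (3.11 ± 0.15). Markers of blood and immune cells had 7 of 9 lower than in rods, 1 higher and 1 not passing (1 higher and 7 lower adjusted over the list alone), with camera adjusted p = 0.0305, adjusted p = 0.612 with an estimated correlation. The chemokine ccl34b.1 (-2.87 ± 0.34, at least 6.88-fold) and the carbonic anhydrase cahz (-2.37 ± 0.39, at least 5.11-fold) fell, and the anion exchanger slc4a1a (1.80 ± 0.32, at least 3.57-fold) rose.

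The other lists had no camera call, with members higher and lower as follows. Cone phototransduction counted 12 and 7 of 26 (12 and 8 adjusted over the list alone), camera adjusted p = 0.0941 (adjusted p = 0.0379 without pineal replicate 2), with grk7a, pde6c and arr3a (5.41 ± 0.17) foremost. Non-visual opsins counted 6 and 1 of 8, camera adjusted p = 0.0768 (adjusted p = 0.036 without pineal replicate 2 and 0.0449 without cone replicate 1), led by parapinopsinb (4.57 ± 0.13) and exorh. Serotonin and melatonin synthesis counted 8 and 2 of 12, camera adjusted p = 0.0826, with aanat1, tph2 and the hydroxylase tph1a (3.22 ± 0.24) foremost. Transcription factors counted 13 and 11 of 40 (14 and 12 adjusted over the list alone), camera adjusted p = 0.82, with the homeobox genes bsx (5.65 ± 0.47) and isl1a (5.17 ± 0.62) and the nuclear receptor nr2f6b (5.24 ± 0.29) higher. Retinoid metabolism counted 11 and 3 of 22, camera adjusted p = 0.0941 (adjusted p = 0.0394 without pineal replicate 2), with the retinol dehydrogenase rdh5 (4.25 ± 0.092), rbp5 (3.76 ± 0.37) and the retinol transporter stra6 (3.32 ± 0.55) higher. Synapse genes counted 7 and 9 of 26, camera adjusted p = 0.699, with the synaptotagmin syt1a (4.83 ± 0.092) and vamp1a (2.83 ± 0.12) higher and snap25a (-2.65 ± 0.10) lower. Glycolysis and creatine kinase genes counted 9 and 9 of 32 (10 and 9 adjusted over the list alone), camera adjusted p = 0.973, with the glucose transporter slc2a3a (2.69 ± 0.024) foremost. Oxidative phosphorylation counted 12 and 13 of 78 (10 and 10 adjusted over the list alone), camera adjusted p = 0.496, with cox4i2 (1.89 ± 0.029) foremost. Cytoplasmic ribosomal proteins counted 7 and 2 of 78 (4 and 0 adjusted over the list alone), camera adjusted p = 0.128, clock genes 6 and 6 of 31 (5 and 6 adjusted over the list alone), camera adjusted p = 0.496, and cell cycle and progenitor genes 8 and 2 of 16, camera adjusted p = 0.283, the last led by insm1a (5.65 ± 0.077) and ascl1a (2.57 ± 0.53).

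Among markers of other cells, those of vessels, connective tissue and epithelium counted 6 and 1 of 10 (7 and 1 adjusted over the list alone), camera adjusted p = 0.0532 (adjusted p = 0.0394 without pineal replicate 2 and 0.037 without cone replicate 1), with the endothelial pecam1a (3.23 ± 0.033) and the keratin krt8 (1.46 ± 0.41) higher. Markers of Mueller glia counted 7 and 4 of 15, camera adjusted p = 0.678, with vimentin, vim (3.07 ± 0.25), and her6 (2.40 ± 0.21) higher. Pigment epithelium and melanophore markers counted 4 and 2 of 7, camera adjusted p = 0.685, with stra6 and the isomerase rpe65a (2.37 ± 0.94) higher. Bipolar cell markers counted 1 and 5 of 7, camera adjusted p = 0.128, where pcp4l1 was higher and samsn1a (-2.70 ± 0.83) and trpm1b (-2.60 ± 0.060) lower. Markers of amacrine, horizontal and ganglion cells and other neurons counted 8 and 7 of 19 (8 and 8 adjusted over the list alone), camera adjusted p = 0.714, with the neurofilament nefma (3.46 ± 0.17), kctd12.1 (3.09 ± 0.035) and pax6a (3.0 ± 0.58) higher. Oligodendrocyte and brain glia markers counted 4 and 3 of 8, camera adjusted p = 0.808, with fabp7a (-2.0 ± 0.74) and slc1a2a (-1.85 ± 0.35) lower and myelin basic protein, mbpb (1.63 ± 0.010), higher. Median centring also gave calls to cone phototransduction (adjusted p = 0.009), non-visual opsins (0.009), retinoid metabolism (0.00987), vessels, connective tissue and epithelium (0.00987) and bipolar cells (0.0432). Testing without the filter on dim probes did so for cone phototransduction (0.00142), non-visual opsins (0.00828), serotonin and melatonin synthesis (0.0128), bipolar cells (0.00828) and ribosomal proteins (0.00213). Median, mean and camera direction differed in sign for transcription factors (median -0.062, mean 0.28, camera down), synapse genes (-0.12, 0.20, down) and glycolysis (0.21, 0.026, down). They also did for neuron markers (-0.12, 0.55, up) and oligodendrocyte markers (0.28, -0.042, up).

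**Figure D2:**
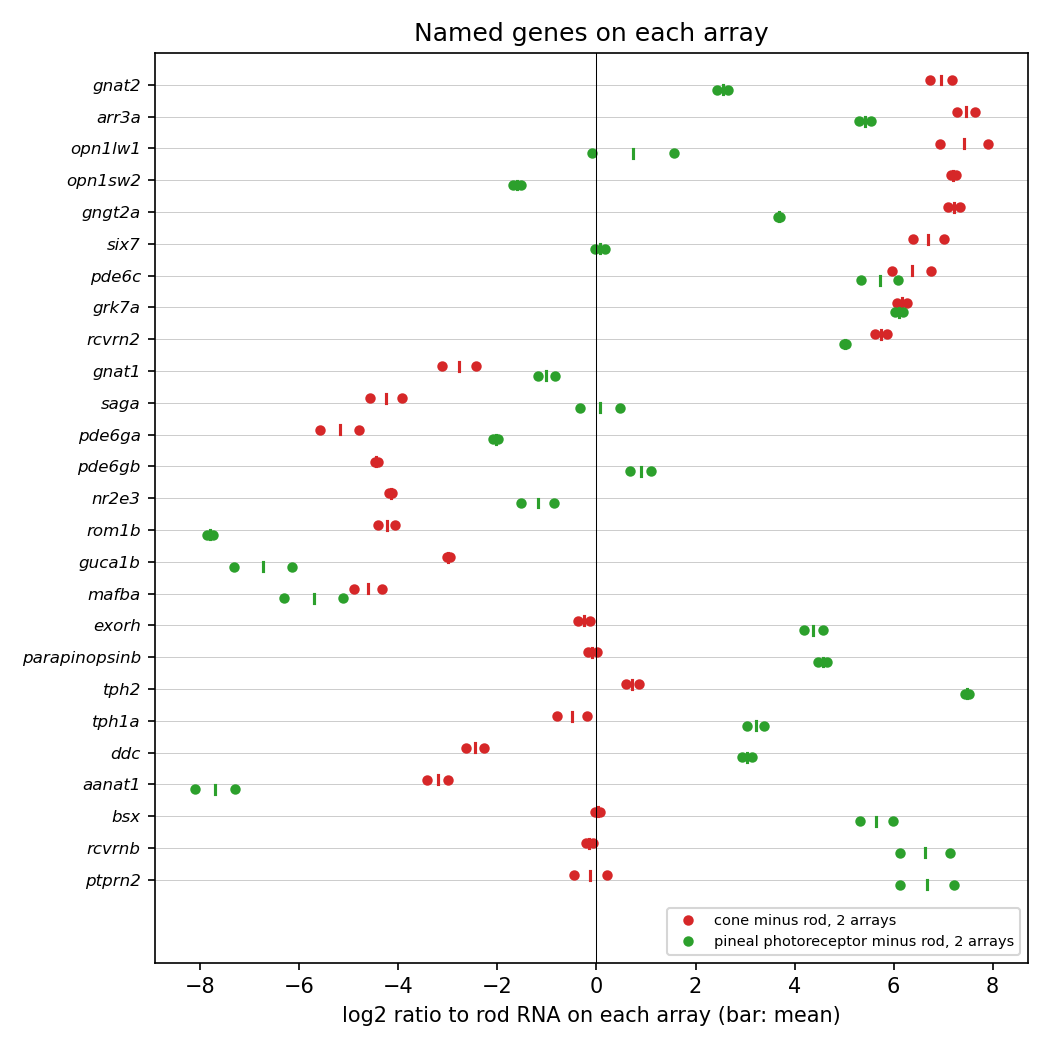
Log2 ratio to rod RNA (horizontal axis) of named genes, 1 point per array, for cones (red) and pineal photoreceptors (green), with the mean of 2 arrays as a bar. Cone opsins opn1lw1 and opn1sw2 lie far right for cones only (7.42 and 7.21), tph2 far right for pineal photoreceptors (7.47), and rom1b left for both (-4.24 and -7.80).

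The third comparison, pineal photoreceptors against cones, was made through the rod RNA on the arrays, and its SD is that of 2 differences between arrays sharing a rod extract. Its adjusted p and counts, unless the replicate block is named, come from the fit without the block, which does not use that sharing. SD and adjusted p therefore rest on different spreads here. Its bounds come from channel levels and for some genes exceed the fold of the contrast through rods. This contrast leaves exorh too low and may leave other bright pineal genes low. By it, the largest rises in pineal photoreceptors were of ptprn2 (6.80 ± 1.25), rcvrnb (6.79 ± 0.82, at least 116-fold), tph2 (6.75 ± 0.25) and pcp4l1 (6.66 ± 0.25). The transcription factor insm1a (6.58 ± 0.54), sult4a1 (6.49 ± 0.090), the hydrolase ahcy (6.03 ± 0.019) and the adenosine kinase adka (5.97 ± 0.094) followed. The largest falls were of gatd3l (-9.34 ± 0.15), the blue opsin opn1sw2 (-8.81 ± 0.051, at least 405-fold), prph2a (-8.66 ± 0.17) and the green opsin opn1mw2 (-8.39 ± 0.054, at least 347-fold). The cone arrestin arr3b (-7.12 ± 0.14), the red opsin opn1lw2 (-7.04 ± 0.85), the green opsin opn1mw3 (-6.83 ± 0.31, at least 346-fold) and the guanylate cyclase activator guca1c (-6.79 ± 0.59) also fell. Adjusted p of these 16 genes lay between 1.84e-06 and 4.11e-05. The red opsins and the green opsins are near-identical copies, and their probes were not shown to separate them.

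Here 3984 genes differed, 2149 higher and 1835 lower in pineal photoreceptors, which put 53.9% of them higher, and median centring with the replicate block put 71.2% of 2906 higher, the block alone 53.9% of 6098. At 2-fold or more, 1164 were higher and 969 lower, and the 2 differences correlated across genes with r = 0.945. The replicate block raised the count to 6098, and leaving out pineal replicate 2 lowered it to 2505.

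In 26 cone phototransduction genes, 3 rose, 18 fell and 5 did not pass (3 higher and 18 lower adjusted over the list alone), with camera adjusted p = 5.12e-09, adjusted p = 0.534 with an estimated correlation. In 18 rod phototransduction genes, 10 rose, 4 fell and 4 did not pass (10 higher and 4 lower adjusted over the list alone), with camera adjusted p = 0.018, adjusted p = 0.664 with an estimated correlation and adjusted p = 0.0621 with the processed signals. Besides rcvrnb, the phosphodiesterase subunit pde6gb (5.34 ± 0.32) and the arrestin saga (4.33 ± 1.03) were higher in pineal photoreceptors. In 12 genes of serotonin and melatonin synthesis, 5 rose, 1 fell and 6 did not pass (7 higher and 1 lower adjusted over the list alone), with camera adjusted p = 0.0206, adjusted p = 0.534 with an estimated correlation and adjusted p = 0.0772 with the processed signals. There tph2 and the decarboxylase ddc (5.50 ± 0.41) rose and aanat1 (-4.49 ± 0.27) fell. In 40 transcription factors, 11 rose, 18 fell and 11 did not pass (12 higher and 19 lower adjusted over the list alone), with camera adjusted p = 0.0206, adjusted p = 0.664 with an estimated correlation and adjusted p = 0.0621 with the processed signals. The homeobox genes bsx (5.63 ± 0.40, at least 63-fold) and isl1a (5.42 ± 0.43) rose and six7 (-6.63 ± 0.58) fell. In 22 genes of retinoid metabolism, 12 rose, 4 fell and 6 did not pass (12 higher and 4 lower adjusted over the list alone), with camera adjusted p = 0.0395, adjusted p = 0.534 with an estimated correlation. That call was lost with the processed signals (adjusted p = 0.0772) and without the filter on dim probes (adjusted p = 0.0616). The retinol dehydrogenase rdh5 (4.29 ± 0.24, at least 34.6-fold), rbp5 (3.52 ± 0.11) and stra6 (3.49 ± 0.94) rose. In 26 synapse genes, 5 rose, 15 fell and 6 did not pass (5 higher and 16 lower adjusted over the list alone), with camera adjusted p = 0.018, adjusted p = 0.534 with an estimated correlation. Against the list's direction syt1a (5.64 ± 0.080) and vamp1a (2.79 ± 0.021) rose, while snap25a (-4.50 ± 0.16) fell. In 78 oxidative phosphorylation genes, 2 rose, 13 fell and 63 did not pass (2 higher and 7 lower adjusted over the list alone), with camera adjusted p = 0.00257, adjusted p = 0.534 with an estimated correlation, and the median of -0.26 turned to 0.064 with median centring. This call was lost with the processed signals (adjusted p = 0.0621) and with median centring (adjusted p = 0.468), and the largest member, cox4i2 (1.40 ± 0.053), rose.

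Lists without a call again had members higher and lower. Outer segment and cilium genes counted 5 and 11 of 47, camera adjusted p = 0.143, with prph2a, prph2b (-6.60 ± 0.90) and rom1b (-3.56 ± 0.34) lower. Non-visual opsins counted 5 and 3 of 8, camera adjusted p = 0.386, with parapinopsinb (4.66 ± 0.0041, at least 30.2-fold) and exorh higher and opn4.1 (-3.24 ± 0.28) lower. Glycolysis and creatine kinase genes counted 7 and 9 of 32, camera adjusted p = 0.578, with ckmt2a (-4.13 ± 0.25), pfkfb3 (-3.09 ± 0.15) and the lactate dehydrogenase ldhbb (-2.65 ± 0.57) lower. Stress and immediate early genes counted 6 and 12 of 32 (8 and 13 adjusted over the list alone), camera adjusted p = 0.227, with ier2b (-3.65 ± 0.072) foremost. Clock genes counted 1 and 4 of 31 (1 and 2 adjusted over the list alone), camera adjusted p = 0.271, with tefa (1.22 ± 0.24) foremost. Cytoplasmic ribosomal proteins counted 4 and 0 of 78 (0 and 0 adjusted over the list alone), camera adjusted p = 0.0659 (adjusted p = 0.0498 with the replicate block, 0.00298 without cone replicate 2 and 0.0262 without pineal replicate 2), and cell cycle and progenitor genes 5 and 1 of 16, camera adjusted p = 0.172, with insm1a and ascl1a (2.36 ± 0.13) higher. Markers of vessels, connective tissue and epithelium counted 5 and 1 of 10 (7 and 1 adjusted over the list alone), camera adjusted p = 0.0569 (adjusted p = 0.0476 with the replicate block, 0.0182 without cone replicate 2 and 0.0455 without pineal replicate 2), with pecam1a (4.49 ± 0.20) foremost. Markers of Mueller glia counted 6 and 3 of 15 (7 and 3 adjusted over the list alone), camera adjusted p = 0.373, with her6 (2.37 ± 0.017) higher and cahz (-2.26 ± 0.26, at least 4.73-fold) lower. Pigment epithelium and melanophore markers counted 4 and 1 of 7, camera adjusted p = 0.315, with stra6 and rpe65a (3.33 ± 0.68) higher. Bipolar cell markers counted 2 and 1 of 7, camera adjusted p = 0.541, with pcp4l1 higher and samsn1a (-2.87 ± 0.63) lower. Markers of amacrine, horizontal and ganglion cells and other neurons counted 7 and 3 of 19 (7 and 4 adjusted over the list alone), camera adjusted p = 0.711, with rbfox1 (-4.09 ± 0.43) lower and pax6a (3.61 ± 0.19) and stmn2a (2.43 ± 0.091, at least 4.74-fold) higher. Blood and immune markers counted 1 and 2 of 9, camera adjusted p = 0.386, with cahz and slc4a1a (1.89 ± 0.22, at least 3.48-fold) foremost, and oligodendrocyte and brain glia markers 4 and 2 of 8, camera adjusted p = 0.386, with mbpb (2.26 ± 0.13) foremost. Median centring also gave a call to vessels, connective tissue and epithelium (adjusted p = 0.0262), and testing without the filter on dim probes to ribosomal proteins (0.000908). Median, mean and camera direction differed in sign for glycolysis (0.14, -0.18, down) and neuron markers (-0.26, 0.24, up).

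**Figure D3:**
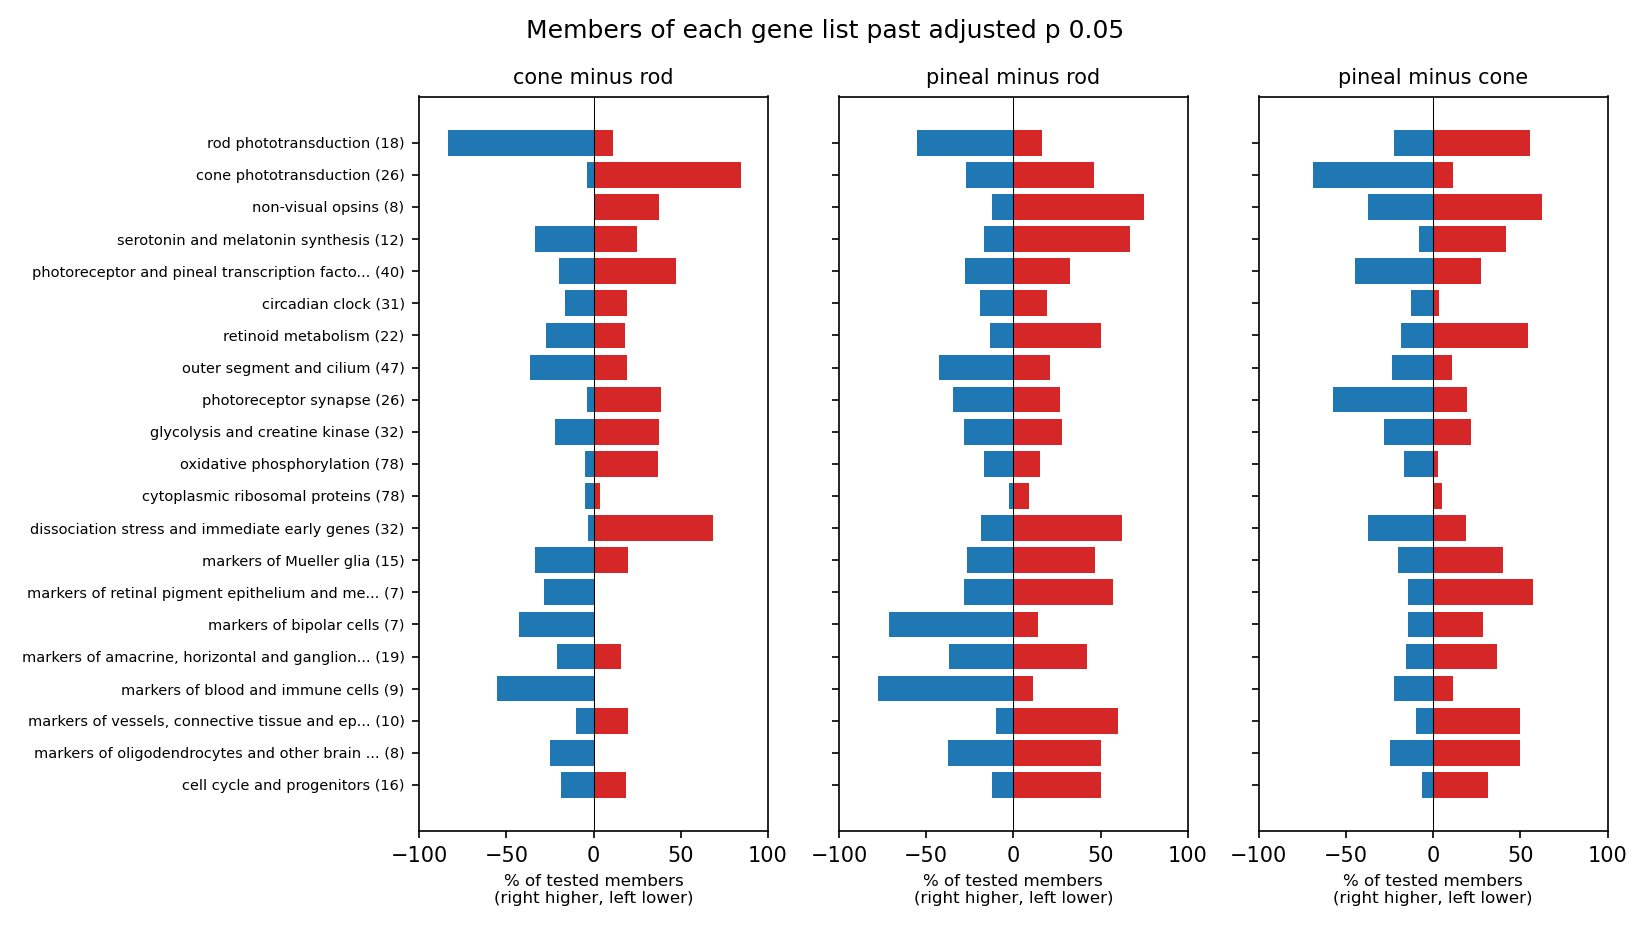
Share of each list's tested members (number in brackets, horizontal axis in percent) that were higher (red, right) or lower (blue, left) at adjusted p 0.05 in each comparison. Cone phototransduction lies right for cones against rods (22 of 26 higher) and left for pineal photoreceptors against cones (18 of 26 lower), and oxidative phosphorylation, whose median sign turned with median centring in both, lies the same way (29 of 78 higher and 13 of 78 lower).

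Genes that set 1 cell type apart from both others were counted from the same tests. In rods 1260 genes were higher than in both other cell types and 1108 lower, in cones 1202 and 710, and in pineal photoreceptors 1685 and 868. These counts depended on the processing. Those higher in rods, in cones and in pineal photoreceptors were 890, 793 and 1230 with the processed signals and 1944, 1772 and 2452 with the replicate block. They were 796, 831 and 1030 without pineal replicate 2. With median centring and the replicate block, chosen after seeing the data, they were 1901, 520 and 1318, so that rods had the most. Median centring alone left 0 in each. The rod genes with the largest smaller difference were mafba, rom1b, ptgs2a, rom1a, the exchanger slc24a4a, the rhodopsin-like rhol, aanat1 and pdca. Their smaller differences ran from 3.1 for pdca to 4.62 for mafba. In cones they were gatd3l, opn1sw2, opn1mw2, prph2a, opn1lw1, six7, opn1mw3 and arr3b, from 6.58 for arr3b to 7.38 for gatd3l. In pineal photoreceptors they were tph2, ptprn2, rcvrnb, pcp4l1, sult4a1, ahcy, adka and insm1a, from 5.65 for insm1a to 6.75 for tph2. The smaller difference of exorh is a low estimate, so its place among the pineal genes is not known. Those of other bright pineal genes may be low in the same way. These smaller differences leave aside that some of the genes lay below background in the dimmer cell type. Some genes missed the threshold without the replicate block and passed with it. They were adka, lower in cones than in rods (-0.31 ± 0.030, adjusted p = 0.0228 against 0.0802), opn1lw1, higher in pineal photoreceptors than in rods (0.73 ± 1.17, 0.000307 against 0.168), and mafba and slc24a4a, lower in pineal photoreceptors than in cones (-1.09 ± 0.43, 0.000226 against 0.0787, and -0.79 ± 0.018, 0.00067 against 0.0508). Each also passed with other settings. The difference of adka passed with the processed signals (-1.01, adjusted p = 0.0226) and an offset of 10 (adjusted p = 0.0362), and those of mafba and slc24a4a with both of these (adjusted p from 0.0157 to 0.0392). That of opn1lw1 passed on its own arrays (adjusted p = 0.0395), with separate channels (adjusted p = 0.0415) and without pineal replicate 2 (adjusted p = 0.011), and was -0.096 without pineal replicate 1. The difference of opn1mw3 between pineal photoreceptors and rods (-0.25 ± 0.079, adjusted p = 0.165) was -2.63 with the processed signals and passed (adjusted p = 0.00162). Pineal photoreceptors were below background for it, and at least 2.07-fold lower by the levels of all rod channels. That bound exceeds the 1.19-fold of the difference because it also draws on the rod channels of the cone arrays, and is no floor for it. Different probes of a gene lay more than 1 log2 apart for 15 of 83 named genes in cones against rods, 25 of 80 in pineal photoreceptors against rods and 18 of 77 in pineal photoreceptors against cones. These totals include genes with 1 kept probe, which cannot disagree, so the share among genes with several probes is higher. Probes had opposite signs for 2, 0 and 1 of the named genes in the same order. Cone against rod, the probes of egr1 ran from 0.60 to 4.45, of gnat2 from 2.89 to 6.95, of prph2a from 2.77 to 6.76 and of fosab from 0.20 to 3.68. Pineal photoreceptor against rod, those of pde6c ran from 0.74 to 5.71 and of pax6a from 0.40 to 3.0.

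Both comparisons with rods were set against each other across genes. Their log2 differences correlated with r = 0.371 and Spearman's rho = 0.401, where genes are not independent replicates. Simulated cell types without any difference from rods, sharing the same rod extracts, gave a mean r of 0.507 over 100 simulations. The spread and covariance put into them came from the arrays' own deviations (r = 0.508), so they return these. The covariance was 0.297 against 0.0150 in the simulations, a difference of 0.282. Arrays sharing no rod extract correlated with r = 0.337 and 0.342, and arrays sharing one with 0.371 and 0.380. Neither the simulations nor these pairs take out rod expression itself, which is subtracted in both comparisons and can correlate them by construction. Of 2924 genes that differed in both comparisons, 1108 were higher in both, 1260 lower in both and 556 opposite. Independent lists would give 658, 458 and 1100, which does not remove the part that the shared rod extracts contribute. Genes high in both were grk7a (6.17 ± 0.13 in cones and 6.10 ± 0.11 in pineal photoreceptors), arr3a and rcvrn2, and rom1b and guca1b (-2.99 ± 0.042 and -6.74 ± 0.83) were low in both. These were chosen after their values were seen.

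**Figure D4:**
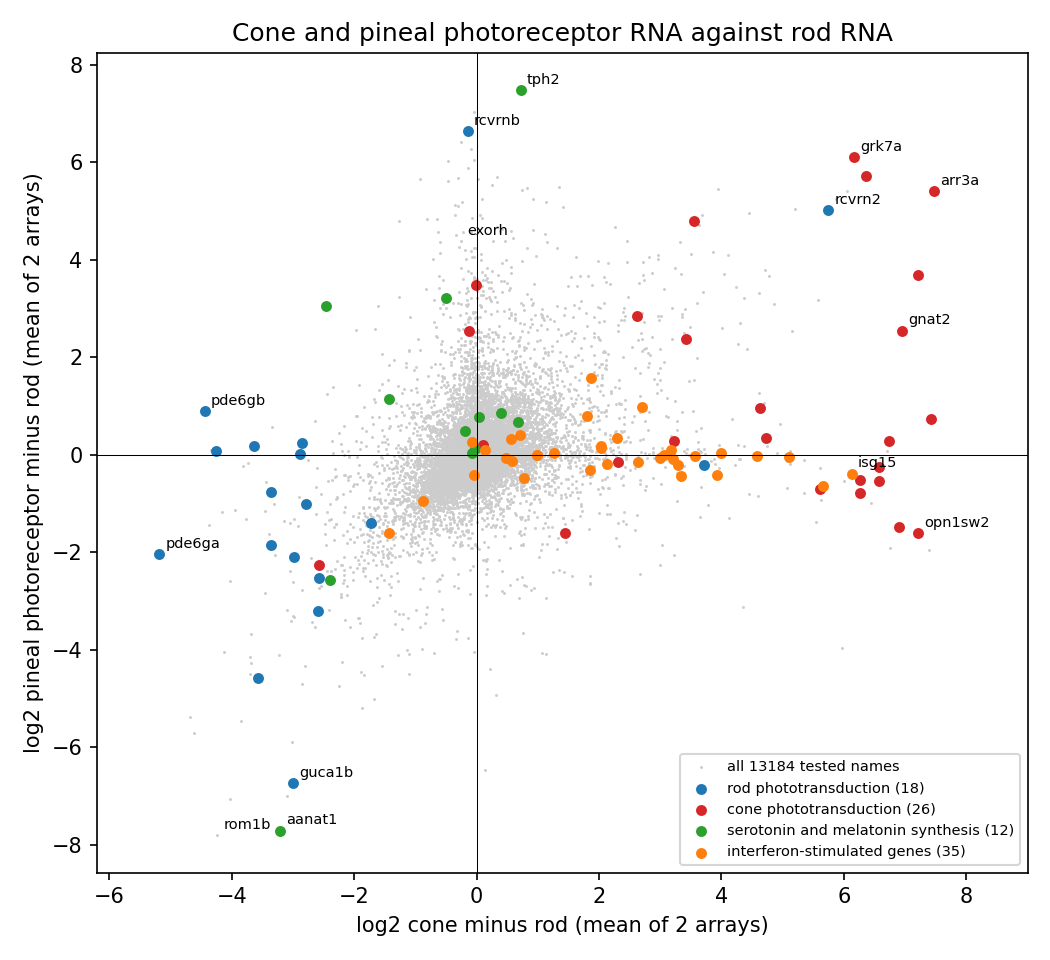
Mean log2 difference from rods over 2 arrays, cones on the horizontal and pineal photoreceptors on the vertical axis, 1 point for each of 13184 tested names, with the members of 4 lists in colour. Genes of cone phototransduction (26, red) spread to the right, and tph2 and rcvrnb stand high near 0 on the horizontal axis, at 7.47 and 6.64.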

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

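Of the tests in this part, only median centring with the replicate block was chosen after the results were seen. Counts of genes different between cones and rods, between pineal photoreceptors and rods, and between pineal photoreceptors and cones are given in that order, from main values of 4966, 5884 and 3984. Median centring left 0, 0 and 0 genes in limma (478, 648 and 326 at an unadjusted p of 0.05, lowest adjusted p 0.638, 0.398 and 1.00) and 0 genes higher in 1 cell type than in both others, against 4147. It leaves a dye trend in the ratios. The median ratio of Cy5 to Cy3 rose from between -0.13 and 0.35 in the dimmest eighth of genes to between 1.05 and 2.0 in the brightest, and the median residual SD was 1.21 against 0.169. With the replicate block, which is also a dye term, that SD fell to 0.137 and the counts were 5698, 5544 and 2906, with 29.0%, 50.4% and 71.2% higher, and 3739 genes higher in 1 cell type. Under median centring the median of all genes was -0.17, -0.017 and 0.18, against 0.0026, 0.032 and 0.030. It moved the correlation of both comparisons with rods from 0.371 to 0.419, and the cause was not tested. A threshold of 2-fold left 1640, 2069 and 2133 genes and adjusted p 0.01 left 3050, 3799 and 2244, fewer by construction. The filter in all 3 cell types, which tests 8718 genes, left 3493, 3838 and 2319. The replicate block gave 7101, 7892 and 6098 and kept every gene called without it. Each comparison on its own arrays gave 6098 for pineal photoreceptors against cones and separate channels 6211, and the cause was not tested for the latter. Besides the calls given in the report, the block changed no other call of a list or a named gene. Leaving out 1 array gave 3501 to 4585 genes for cones against rods, 3284 to 6367 for pineal photoreceptors against rods, 2505 to 3757 for pineal photoreceptors against cones and 2657 to 3758 set apart in 1 cell type. In the last 3 the lowest count came without pineal replicate 2, where the lone array is assumed to vary like the others. The other planned settings kept counts within 1.5 times, the lowest being 3999, 4797 and 2934 with the processed signals, and 2913 set apart in 1 cell type. List calls numbered 7, 4 and 7. An estimated correlation left 0, 0 and 0 (1, 0 and 1 at an unadjusted p of 0.05, and fry passed 9, 11 and 11). That alternative has 2 residual degrees of freedom and little power. For pineal photoreceptors against rods the processed signals left 2, median centring 9, no filter 9 and leaving out 1 array 4 to 8, the highest without pineal replicate 2. For pineal photoreceptors against cones the processed signals left 2. The cause was not tested for these lists. Of 4474 alternative values of 240 named differences of 133 genes, 4040 kept direction and side of the threshold, 389 no longer passed (228 of them with median centring), 35 now passed, 10 that had not passed changed sign, and 0 that had passed reversed. These alternatives are not independent, so the tally overstates how many separate checks were made. The series table repeats the processed signals, and the stricter thresholds keep the main difference and cannot change its sign. In comparisons with rods, leaving out an array of the cell type not compared repeats the fit on their own arrays. With 28.7% to 43.8% of features well above background per channel, dim genes have bounds at most.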

Other observations

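All tests weighed in this part were chosen after the results they bear on were seen. Rod phototransduction transcripts were not all lowered alike in pineal photoreceptors and cones, as levels in percent of rods show. The genes were chosen after their values were seen. In pineal photoreceptors the mean level of the transducin gamma gngt1 was 113% and of the phosphodiesterase subunit pde6gb 185%, and the arrestin saga and the phosphodiesterase pde6a differed from rods by 0.073 ± 0.57 and 0.25 ± 0.000067 on the log2 scale, not passing, while the transducin alpha gnat1 stood at 49.6% and the nuclear receptor nr2e3 at 44.1%. The disc-rim genes rom1a and rom1b and the cyclase activator guca1b stood at 0.746%, 0.448% and 0.937%, against 6.11%, 5.30% and 12.6% in cones. In cones gnat1 stood at 14.6%, saga at 5.25% and pde6ga at 2.74%, the last at 24.3% in pineal photoreceptors. These are levels in the sorted RNA, and whether rods were present in the cone or pineal sort was not tested, the rho probe giving no signal. Others were lowered more alike in cones and pineal photoreceptors, gnb1a to 30.1% and 37.7%, sagb to 16.7% and 17.4% and grk1a to 16.7% and 10.9%.

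Recoverin genes parted between the cell types. Against rods, rcvrn2 was higher in cones (5.74 ± 0.17) and pineal photoreceptors (5.02 ± 0.031), as was rcvrn3 (3.55 ± 0.37 and 4.80 ± 0.15). The gene rcvrnb was higher in pineal photoreceptors alone (6.64 ± 0.72, with -0.15 ± 0.097 in cones, below background and at least 1.07-fold lower, not passing), and rcvrna was lower in cones alone (-2.88 ± 0.18, with 0.015 ± 0.63 in pineal photoreceptors not passing). Pineal photoreceptors against cones passed for each of them (-0.72 ± 0.14 for rcvrn2, 1.25 ± 0.22 for rcvrn3, 6.79 ± 0.82 and at least 116-fold for rcvrnb and 2.90 ± 0.46 for rcvrna, limma adjusted p from 2.39e-05 to 0.0193). Higher than in rods in both cones and pineal photoreceptors were also the nuclear receptor nr2f6b (5.87 and 5.24), kctd12.1 (4.85 and 3.09), the matrix proteoglycan impg2a (3.35 and 2.89), the ciliary tmem237a (2.74 and 2.17), crb2b (2.80 and 1.81) and arl3l1 (1.48 and 1.71). These genes were chosen after their values were seen.

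Genes induced by interferon were higher in cone RNA than in rod RNA, with a median of 2.03 over 35 genes (4.31 with the processed signals). Immune cells in the cone sort are argued against by markers of blood and immune cells, whose median was -0.52 (-2.62 with the processed signals and -1.06 with an offset of 10) with 0 of 9 higher in limma and 5 lower. A single extract or dye is argued against by the medians without the 4 genes first noticed, the lower being 1.88 over both cone arrays. In pineal photoreceptors against the same rod extracts the median of these 31 genes was -0.0074, so as a set they were not lower in rods. For dim members a ratio near 0 shows little. Of the 31, 12 lay below background in 1 cell type in cones against rods and 17 in pineal photoreceptors against cones. Whether the rod extracts were low in those cannot be told. A difference between the fish of the lines, such as infection, stays open, since each cell type came from 1 line. So does a difference between the cell types themselves, which was not tested apart from the line, and it may be either.

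Of 32 stress and immediate early genes, 22 were higher and 1 lower in cones than in rods and 20 higher and 6 lower in pineal photoreceptors, though neither camera call held with an estimated correlation (adjusted p = 0.483 and 0.612). That alternative has 2 residual degrees of freedom and little power. Rod extracts differing from each other are argued against by the lowest median of the 4 arrays, 0.68. Split after the values were seen, 18 immediate early members had medians of 1.62 in cones and 0.33 in pineal photoreceptors, where 10 of the 18 lay above 0 on each array, and 8 heat-shock members 0.85 and 1.38. The largest difference of the medians, immediate early minus heat-shock, was -1.04, and with members going both ways it leaves open whether this could be a general stress response. Time or handling between dissection and lysis and a difference between the cell types also stay open, since each cell type came from 1 line.

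Rod RNA gave little exorh signal on the cone arrays, well above background for rod extract 2 only, and a clear one on the pineal arrays. Its level after loess and Aquantile was 5.33 or more higher there on the log2 scale for the same extracts. That argues against rod transcripts binding the probe. Before dye normalization, the rise over the cone arrays was 1.25% and 22.3% of the pineal signal for rod extracts 1 and 2. Over 16 other genes bright in pineal and dark in rod RNA its medians were 0.154% and 1.95%. Rod RNA carried Cy3 in extract 1 and Cy5 in extract 2, so these shares cannot be compared between the extracts. After loess, exorh was 4.57 and 4.19 higher in pineal than in rod RNA on the log2 scale, for rod extracts 1 and 2. Spillover or pineal RNA reaching all genes at 1 share is argued against as the whole signal, since 7 of the 16 had under 0.1 of the share of exorh in both extracts, among them tph2 (0.0772% and 1.66%), ptprn2 (0.0385% and 0.064%) and rcvrnb (0.108% and 0.439%). Others came near or above it, kcnd3 the most with 2.25% and 19.1%, so spillover of the bright channel and pineal RNA in the rod RNA of these arrays may each contribute a part and cannot be told apart. The medians came to 0.123 of the share of exorh or less for both, which sets no limit, since the genes differ widely.

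Outside exorh, rod levels on cone and pineal arrays correlated across genes with r = 0.993 and 0.996, and 8 of 13183 genes rose and 7 fell more than 2-fold in both extracts. A correlation over all genes does not show that genes bright in pineal RNA were unaffected. Of the 16 such genes above, 0 and 5 gained over 5% of their pineal signal for rod extracts 1 and 2, before dye normalization.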
